A study of Mus musculus with 8 samples.

How the data were processed

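Gene expression was measured by RNA sequencing in 8 lysates of mouse heart ventricle. Per the labels, all 8 libraries came from male mice of 12 weeks, homozygous for floxed alleles of Med13 and Med13l and fed chow with tamoxifen, and 4 weeks had passed since tamoxifen. The genotype label puts 4 libraries in the cre_positive group, which carries a cardiomyocyte-specific Cre recombinase meant to remove the floxed parts of both genes, and 4 in the cre_negative group, which carries the floxed alleles without Cre. The Cre line is not named in the labels. RNA was prepared as stranded total RNA libraries after depletion of ribosomal RNA, per the labels' protocols. Libraries are named here by group and by the sample number of their titles.

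The deposited values are FPKM (fragments per kilobase of transcript and per 1e+06 mapped fragments), 1 value per gene symbol and library, made by the authors with Cufflinks, per the submitters' processing notes. The same notes list Bowtie2 2.2.6 and the mouse build mm10. Aligner settings, the gene annotation, the use of strand in counting and the filter applied before deposit are not given in the sources used here. The table holds 24341 genes. Its lowest value is 0.01, which stands in 32.6% to 39.0% of the genes of each library. It is taken here to fill in for values too low to estimate, which the sources used here do not state. None of the 3151 genes of 500 bases or more with a median of at least 20 FPKM was at that value in any library. In 6 cells of 3 genes (Ttn, Ldb3 and Cacna2d1) a word stands in place of a number. These cells were treated as missing, and the 3 genes were left out of the gene list tests. No gene encoded by mitochondrial DNA is among the genes used here, so that fixed list of 13 genes had no member to test. Coordinates are the mm10 loci of the table, with the start moved to count from 1. After that step 11860 gene starts equalled those of the GRCm38 RefSeq table, against 680 as written.

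The number of fragments per library is not part of the table and was estimated. For 8112 genes with 1 annotated transcript of 500 to 4000 bases, FPKM multiplied by transcript length clusters at the value of a single fragment, and the place of that cluster gives the library size. In units of 1e+06 fragments, the estimate was 6.85, 15.4, 5.55 and 5.47 for cre_negative libraries 1 to 4, and 4.51, 8.67, 23.7 and 22.7 for cre_positive libraries 1 to 4. At 1 FPKM a transcript of 2 kb then rests on 9.02 to 47.3 fragments, so counting error is large for genes near that level. A count of 0 allows up to 3 fragments, which is 0.0634 to 0.333 FPKM for such a transcript. These limits cover counting error only. The level of the ribosomal precursor Rn45s parted the libraries into a set of 5 (cre_negative 1, 3 and 4, cre_positive 1 and 2) with 396 to 1053 FPKM and a set of 3 (cre_negative 2, cre_positive 3 and 4) with 10.3 to 16.0 FPKM, on either side of 100 FPKM. The set of 3 also had the highest estimated depth. It was treated as a library batch found in the data, and both batches hold libraries of both groups.

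The groups were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean), for the 11688 genes with a mean of at least 1 FPKM over the 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Standard errors come from the same model, and levels are given as mean and SD of the deposited FPKM. Fixed gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 4 tested genes. Members of each list are counted by their call over all genes tested and again with p adjusted over the list alone. Cell type scores are the mean of log2(FPKM + 1) over the markers of a list, compared by an exact two-sided permutation test over the 70 assignments of 8 libraries to groups of 4, for which 0.0286 is the smallest p possible. Only lists with at least 4 tested markers were given a score.

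Tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Med13 and Med13l, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap, a set of cardiac genes (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Ppargc1a) and Esr1, part of which is carried by tamoxifen-inducible Cre fusions. For each list it names up to 4 called members with the largest change and, where fewer than 2 were called, the 2 most abundant members. Only part of the genes the rule names are described in the text, and the result of 1 of them is not reported here. Other genes named in the text, as further members of a list or outside any list, were chosen after their values were seen.

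On 10 simulated tables of 11685 genes for the comparison of cre_positive with cre_negative, each with 200 genes changed, the procedure recovered 52.0% of changes of 0.5 on the log2 scale and 92.8% of changes of 1, with 5.08% unchanged genes among those called and 0 calls in the wrong direction. It called 10 of 10 planted lists, whose genes were all raised alike, and 0 of 190 unchanged lists. Noise was drawn independently for each gene, while the correlation estimated in the data was 0.507 for fatty acid genes and 0.410 for respiratory chain genes. The simulated tables therefore did not test false calls of lists with correlated genes. In the data, camera with the preset correlation called lists even in the 18 splits with 2 libraries of each group. There the median was 4 lists and the highest 8, so its p-values for lists can be too small. The recovery holds for tables with 200 changed genes, whereas 39.2% of genes were called in the data. Changes were planted only in genes above a minimum control level, so recovery among the lowest tested genes was not tested.

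Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter or a minimum mean of 5 FPKM, median ratio scaling, quantile normalization, scaling to a fixed sum, eBayes without the trend or with robust estimation, library weights, a block for the sample number, leaving out each library, leaving out the 2 libraries whose column names lack the word trim, averaging cre_negative libraries 1 and 2, camera with an estimated correlation, and fry. The fixed sum was taken without small RNA features, ribosomal protein genes and the genes with missing cells. Alternatives chosen after seeing the data were a batch term, the 5 libraries with high Rn45s alone, removal of each library's trend with transcript length and GC content, leaving out small RNA features, and leaving out the 2 libraries with atrial transcripts. The libraries named 2M and 2M-2 (cre_negative 1 and 2) differed by an SD of 0.361 in their log2 ratio, within the range of 0.236 to 0.476 over all pairs of a group. They were kept as 2 samples. They also differ in Rn45s level and estimated depth, which could widen this SD, so it does not show that they are separate. Nothing in the labels says that each library came from a separate animal, and p-values then measure only the spread between these samples. Figures and the preparation of values used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.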

Results

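RNA from the heart ventricle was sequenced in 8 libraries, 4 from cre_positive mice, in which a tamoxifen-inducible Cre acts in cardiomyocytes on floxed Med13 and Med13l, and 4 from cre_negative mice with the same floxed alleles. Med13 and Med13l encode alternative subunits of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The comparison asks how transcript levels of the ventricle differ when cardiomyocytes of adult male mice carry a Cre meant to delete parts of both genes. Estimated depth ran from 4.51 to 23.7 in units of 1e+06 fragments per library, and 11540 to 11635 genes per library had at least 1 FPKM.

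Transcripts of both targeted genes were lower in each cre_positive library than in each cre_negative library. Med13 (chromosome 11, 86267033 to 86357596, mm10) stood at 11.05, 10.4, 15.3 and 11.4 FPKM in cre_negative libraries 1 to 4 and at 8.73, 8.24, 8.16 and 7.39 FPKM in cre_positive libraries 1 to 4. Med13l (chromosome 5, 118560330 to 118765438, mm10) stood at 4.38, 4.62, 6.13 and 4.54 FPKM in cre_negative and at 2.59, 2.35, 2.59 and 2.54 FPKM in cre_positive libraries. Med13 fell from 12.0 ± 2.23 to 8.13 ± 0.554 FPKM (SD, n = 4 per group), a log2 change of -0.50 with an SE of 0.12 and a limma adjusted p of 0.00612. Med13l fell from 4.92 ± 0.814 to 2.52 ± 0.113 FPKM (SD, n = 4 per group), a log2 change of -0.74 with an SE of 0.11 and a limma adjusted p of 3.2e-04. The exact two-sided permutation p was 0.0286 for each gene, the smallest this design allows. Among the 5 libraries with high Rn45s and the 3 with low Rn45s, the log2 change was -0.51 and -0.37 for Med13 and -0.78 and -0.66 for Med13l. The values cover whole genes and all cell types of the ventricle, and the deleted exons were not measured separately. The call for Med13 was lost under scaling to a fixed sum (log2 change -0.21, adjusted p = 0.185) and in the 5 libraries with high Rn45s alone (adjusted p = 0.0529).

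Ventricles of cre_positive mice had higher transcript levels of both natriuretic peptides and lower levels of a calcium pump, a potassium channel subunit and many genes of fatty acid oxidation. Nppb, which encodes the natriuretic peptide BNP, rose from 195 ± 51.7 to 1436 ± 189 FPKM, and Nppa, which encodes ANP, from 587 ± 88.1 to 3577 ± 878 FPKM (SD, n = 4 per group). Atp2a2, the calcium pump SERCA2 of the sarcoplasmic reticulum, fell from 3745 ± 132 to 611 ± 72.3 FPKM, and Kcnip2, a subunit of the channel for the transient outward potassium current, from 66.6 ± 7.35 to 1.69 ± 0.501 FPKM. In fatty acid uptake and oxidation 23 of 27 genes fell and 1 rose (camera adjusted p = 2.57e-13, adjusted p = 0.190 with an estimated correlation). Among extracellular matrix and TGF-beta genes 27 of 34 rose and 0 fell (camera adjusted p = 2.14e-14, adjusted p = 0.142 with an estimated correlation), with Cilp, Eln, Col8a1 and Comp rising most. Of 11688 genes tested, 2307 were called higher and 2269 lower, in all 39.2%. A log2 change of 1 or more was reached by 362 of the higher genes and one of -1 or less by 332 of the lower genes. Values did not overlap between the groups for 4437 genes, or 38.0% of those tested, where chance gives 2.86%. Of 4575 called genes with a value in both Rn45s batches, 4571 had the same direction in both, which is no independent check, since the calls rest on the same libraries and the low-Rn45s batch holds 1 cre_negative library. With the batch as a term in limma, 2485 genes were called higher and 2495 lower. The 10 most abundant genes held 18.7% ± 0.302 of the FPKM sum in cre_negative and 14.1% ± 0.231 in cre_positive libraries (SD, n = 4 per group). Scaling each library to a fixed sum, taken without small RNA and ribosomal protein genes, moved the median log2 change of all genes from -0.01 to 0.26. The calls became 5458 higher and 1011 lower, so that 84.4% of calls were higher against 50.4% without that scaling. Directions are therefore relative to the deposited scale, and 4371 of the 4576 called genes kept theirs under that scaling.

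The largest rises on the log2(FPKM + 1) scale, among called genes whose groups did not overlap, were those of Gdf15 (4.66), Cnn1 (4.11), Ifi27l2b (3.86) and Ctgf (3.49). Gdf15, a secreted stress cytokine, went from 1.62 ± 2.46 to 51.0 ± 12.2 FPKM (SD, n = 4 per group), with cre_negative library 4 at 5.29 FPKM and the other controls at 0.752 FPKM or less. Cnn1, an actin-binding protein best known from smooth muscle, went from 2.41 ± 1.56 to 55.2 ± 13.0 FPKM. The other genes with the largest rises were Sv2b, Tnni1, Nlrc3, Nmrk2, Rnd1, Esr1, Cda and 2200002D01Rik, with log2 changes of 3.27, 3.19, 3.17, 3.13, 3.11, 3.10, 3.04 and 3.00. Nmrk2, a nicotinamide riboside kinase of muscle, rose from 4.17 ± 2.22 to 41.5 ± 6.35 FPKM. Esr1, the gene of estrogen receptor alpha (chromosome 10, 4611989 to 5005633, mm10), rose from 0.468 ± 0.335 to 12.2 ± 5.20 FPKM, and inducible Cre proteins are commonly fusions with part of an estrogen receptor. The largest falls were those of Kcnip2 (-4.66), Ces1d (-4.38), Lrtm1 (-3.40), Ryr2 (-2.95), Pln (-2.92), Fhl2 (-2.85), Scn4b (-2.62), Atp2a2 (-2.62), Rpl3l (-2.50), Lrrc15 (-2.43), Lrrc4b (-2.39) and Itgb6 (-2.38). Ces1d, a carboxylesterase that hydrolyses lipids, fell from 78.4 ± 9.62 to 2.89 ± 1.04 FPKM, and Rpl3l, a ribosomal protein specific to heart and skeletal muscle, from 148 ± 9.39 to 25.7 ± 5.42 FPKM.

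**Figure D1:**
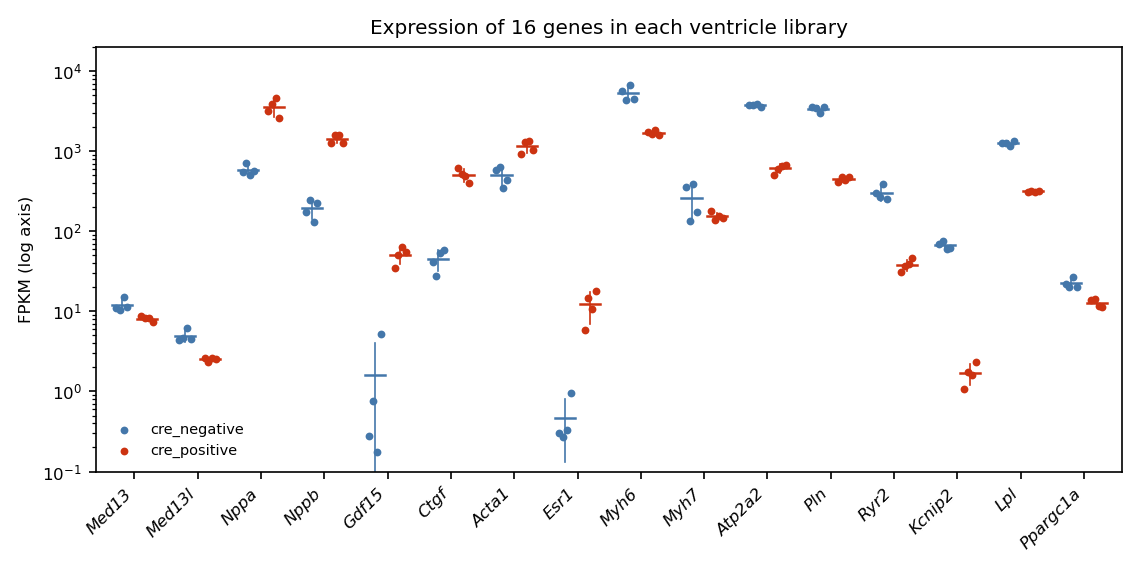
FPKM on a log axis in each of the 4 cre_negative and 4 cre_positive libraries for 16 named genes, with points for libraries, horizontal lines for the group mean and vertical lines for the SD, which for Gdf15 reaches below the axis. Nppa, Nppb, Acta1 and Esr1 sit higher in each cre_positive library than in any control, Myh6, Atp2a2, Med13 and Med13l lower, and the groups overlap for Myh7.

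In the list of cardiac stress and fetal genes, 10 of 11 members rose and 0 fell, over all genes and adjusted over the list alone, at a median log2 change of 2.00 (camera adjusted p = 4.04e-08, adjusted p = 0.0544 with an estimated correlation). The median was 2.08 in the high-Rn45s and 2.21 in the low-Rn45s libraries. Acta1, skeletal alpha-actin, rose from 502 ± 135 to 1158 ± 197 FPKM, and Ctgf, a matricellular growth factor gene, from 45.2 ± 13.5 to 506 ± 89.7 FPKM (SD, n = 4 per group). Tnni1, the slow skeletal troponin I of the fetal heart, was listed at 0.01 FPKM in 3 controls and at 0.0659 FPKM in cre_negative library 2, against 8.72 ± 3.36 FPKM in cre_positive libraries. The member not called was Myh7, the slow beta-myosin heavy chain of the fetal mouse ventricle, at 262 ± 127 FPKM in cre_negative and 155 ± 16.1 FPKM in cre_positive libraries (log2 change -0.62, limma adjusted p = 0.126). It was called lower in 4 of 26 other settings, among them leaving out cre_negative library 2 (log2 change -0.90, adjusted p = 0.0151). Its adult counterpart Myh6 fell from 5277 ± 1092 to 1704 ± 88.9 FPKM. Levels of both are uncertain where reads fit either gene, since they are neighbours with closely similar sequence. Mhrt, an antisense transcript overlapping Myh7, fell from 60.1 ± 12.0 to 12.0 ± 1.84 FPKM, and the use of strand in counting is not given in the sources used here.

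Many genes of contraction and excitation fell. In the sarcomere and Z disc list 13 of 21 members fell and 1 rose, with the same counts adjusted over the list alone. The sarcomere median was -0.53 (camera adjusted p = 6.86e-05, adjusted p = 0.103 with an estimated correlation). The ventricular light chain Myl2 fell from 20614 ± 592 to 6941 ± 353 FPKM, Myl3 from 5446 ± 554 to 1722 ± 291 FPKM and cardiac troponin T (Tnnt2) from 6393 ± 683 to 2344 ± 497 FPKM (SD, n = 4 per group). The intermediate filament gene Des rose from 557 ± 21.1 to 1181 ± 146 FPKM, while cardiac actin (Actc1) stood at 10403 ± 1251 and 10513 ± 726 FPKM and was not called. Actc1 was called higher after quantile normalization (log2 change 0.69) and under scaling to a fixed sum (0.34). Of 15 calcium handling genes 10 fell and 0 rose, or 10 and 1 adjusted over the list alone. The calcium handling median was -0.39 (camera adjusted p = 3.26e-05, adjusted p = 0.103 with an estimated correlation). The ryanodine receptor Ryr2, which releases calcium from the sarcoplasmic reticulum, fell from 303 ± 61.7 to 38.2 ± 6.18 FPKM, and phospholamban (Pln), which restrains SERCA2, from 3408 ± 255 to 449.7 ± 31.7 FPKM, with cre_negative library 3 lowest of the controls at 3028 FPKM. Of 18 ion channel and connexin genes 13 fell and 1 rose, with the same counts adjusted over the list alone. The ion channel median was -0.85 (camera adjusted p = 4.41e-06, adjusted p = 0.103 with an estimated correlation). The gap junction gene Gja1 fell from 237 ± 32.4 to 50.9 ± 3.78 FPKM and the sodium channel subunit Scn4b from 8.16 ± 3.14 to 0.430 ± 0.164 FPKM. Medians in the high-Rn45s and low-Rn45s libraries were -0.48 and -0.41 for the sarcomere, -0.33 and -0.30 for calcium handling and -0.95 and -0.57 for ion channels. Under scaling to a fixed sum the medians shrank to -0.21 for the sarcomere, -0.0761 for calcium handling and -0.55 for ion channels. The sarcomere list was no longer called after quantile normalization (median -0.11, adjusted p = 0.509).

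Among 15 cardiac transcription factors 5 fell and 0 rose, over all genes and adjusted over the list alone, and the list was not called (camera adjusted p = 0.128), though it was called lower once length and GC trends were removed (adjusted p = 0.0331). Myocd, a coactivator of serum response factor, fell from 20.1 ± 3.92 to 9.98 ± 0.895 FPKM and Tbx5 from 7.05 ± 1.27 to 3.69 ± 0.362 FPKM (SD, n = 4 per group). Besides Med13 and Med13l, none of the 7 kinase module genes was called, over all genes or adjusted over the list alone (camera adjusted p = 0.403). Of 26 core Mediator subunits 4 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.672). Med10 rose from 15.6 ± 1.25 to 21.5 ± 1.01 FPKM, while Med4 fell from 25.3 ± 2.60 to 18.1 ± 1.03 FPKM and Med1 from 18.5 ± 2.48 to 14.1 ± 0.565 FPKM. Under scaling to a fixed sum the calls of Med4 (log2 change -0.15, adjusted p = 0.165) and Med1 (-0.0688, adjusted p = 0.615) were lost.

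Most tested genes of mitochondrial energy supply fell. In fatty acid uptake and oxidation 23 of 27 genes fell and 1 rose, with the same counts adjusted over the list alone. The fatty acid gene median was -1.17 (camera adjusted p = 2.57e-13, adjusted p = 0.190 with an estimated correlation). Lipoprotein lipase (Lpl) fell from 1268 ± 65.9 to 315 ± 5.49 FPKM, the thiolase Acaa2 from 720 ± 150 to 181 ± 25.2 FPKM and the acyl-CoA synthetase Acsl1 from 538 ± 36.9 to 174 ± 11.7 FPKM (SD, n = 4 per group), while Cpt1a rose by 0.60 on the log2 scale. Each of the 18 TCA cycle genes fell, over all genes and adjusted over the list alone. Their median was -0.68 (camera adjusted p = 5.44e-11, adjusted p = 0.103 with an estimated correlation). Idh3b fell from 575 ± 50.0 to 245 ± 22.5 FPKM and Sdha from 699.9 ± 10.7 to 340 ± 17.9 FPKM. Of 73 nuclear genes of the respiratory chain 55 fell and 0 rose, or 61 and 0 adjusted over the list alone. The respiratory chain median was -0.60 (camera adjusted p = 5.51e-17, adjusted p = 0.223 with an estimated correlation). Cox7a1, the muscle form of a cytochrome c oxidase subunit, fell from 3208 ± 412 to 1056 ± 171 FPKM and the complex I subunit Ndufa5 from 899.5 ± 28.9 to 405 ± 37.2 FPKM. In the breakdown of branched-chain amino acids 14 of 16 genes fell and 0 rose, with the same counts adjusted over the list alone. The amino acid gene median was -0.74 (camera adjusted p = 1.45e-08, adjusted p = 0.103 with an estimated correlation). Mccc2 fell from 49.0 ± 3.19 to 18.1 ± 1.34 FPKM. Of 18 PGC-1, ERR and PPAR regulators, which drive transcription of such genes, 11 fell and 0 rose, with the same counts adjusted over the list alone. The regulator gene median was -0.44 (camera adjusted p = 3.02e-04, adjusted p = 0.103 with an estimated correlation). Ppargc1a fell from 22.3 ± 3.16 to 12.8 ± 1.43 FPKM, Ppargc1b from 9.08 ± 1.61 to 2.03 ± 0.302 FPKM and Ppara from 16.8 ± 2.01 to 7.27 ± 0.965 FPKM. In the high-Rn45s and low-Rn45s libraries the medians were -1.22 and -1.27 for fatty acids, -0.69 and -0.76 for the TCA cycle, -0.60 and -0.74 for the respiratory chain, -0.78 and -0.76 for branched-chain amino acids and -0.46 and -0.44 for the regulators. Scaling to a fixed sum shrank the medians to -0.36 for the TCA cycle, -0.28 for the respiratory chain, -0.43 for branched-chain amino acids and -0.13 for the regulators, and quantile normalization gave -0.45 for the TCA cycle and -0.26 for the respiratory chain. Beside these falls, the score of fibroblast markers was higher by 0.51 and that of smooth muscle markers by 0.65 on the log2 scale. The latter rested on Cnn1 (4.11) and Acta2 (2.01), as the median of the 10 smooth muscle markers was 0.07 and the list was not called (camera adjusted p = 0.344).

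Glucose and lipid genes went both ways. Of 19 genes of glycolysis and glucose uptake 9 rose and 6 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.537), although the list was called higher after quantile normalization (adjusted p = 0.0222). The platelet phosphofructokinase Pfkp rose from 26.2 ± 4.07 to 106 ± 8.91 FPKM and the glucose transporter Slc2a1 from 5.59 ± 1.38 to 12.9 ± 0.872 FPKM, whereas the muscle forms Hk2 and Eno3 fell, from 97.9 ± 13.9 to 36.9 ± 3.11 FPKM and from 1253 ± 110 to 503 ± 77.4 FPKM (SD, n = 4 per group). In lipid synthesis and sterol genes 5 of 19 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.618). There Dgat2, an enzyme of triglyceride synthesis, fell from 165 ± 34.0 to 39.6 ± 11.6 FPKM and Gpam from 108 ± 19.5 to 47.0 ± 7.91 FPKM. The median of this list was 0.08, while its mean was -0.17 and camera pointed down.

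**Figure D2:**
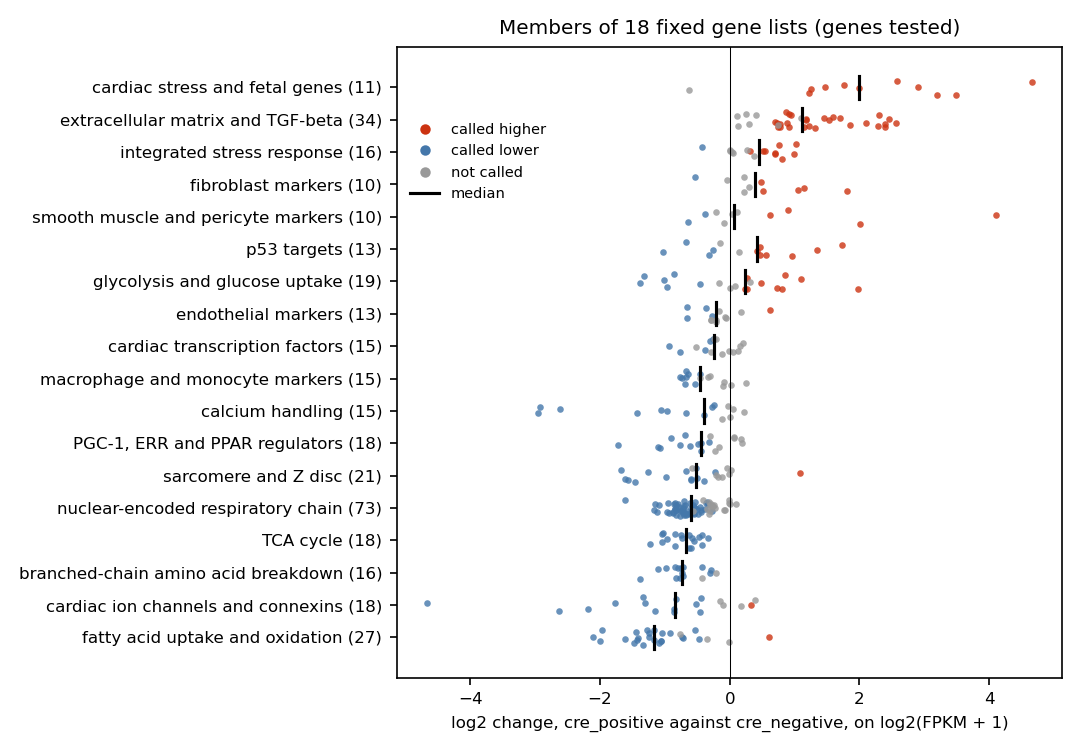
Log2 change of each tested gene of the fixed lists, cre_positive against cre_negative on the log2(FPKM + 1) scale, with 1 point per gene and a mark for the list median. Numbers in brackets count the genes tested and colours show the call, and the points of the TCA cycle (median -0.68) all lie below 0 and those of the extracellular matrix (median 1.12) all above it.

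Extracellular matrix genes rose, and markers of cell types other than cardiomyocytes moved in different directions. In the list of extracellular matrix and TGF-beta genes 27 of 34 rose and 0 fell, or 29 and 0 adjusted over the list alone. The matrix gene median was 1.12 (camera adjusted p = 2.14e-14, adjusted p = 0.142 with an estimated correlation). Cilp, a matrix protein made by cardiac fibroblasts, rose from 8.61 ± 3.76 to 53.4 ± 9.21 FPKM, elastin (Eln) from 5.42 ± 1.13 to 35.8 ± 14.1 FPKM, Col8a1 from 14.8 ± 2.73 to 82.0 ± 14.6 FPKM and Comp from 1.60 ± 0.575 to 12.8 ± 4.02 FPKM (SD, n = 4 per group). The list's median was 1.02 in the high-Rn45s and 1.25 in the low-Rn45s libraries. Of 10 fibroblast markers 5 rose and 1 fell, or 8 and 1 adjusted over the list alone. The fibroblast marker median was 0.39 (camera adjusted p = 0.0191, adjusted p = 0.263 with an estimated correlation). Mfap5 rose from 17.1 ± 4.95 to 61.1 ± 10.6 FPKM and Dpt fell from 57.8 ± 2.73 to 39.7 ± 1.58 FPKM. Of 15 macrophage and monocyte markers 8 fell and 0 rose, or 9 and 0 adjusted over the list alone. The macrophage marker median was -0.46 (camera adjusted p = 0.00285, adjusted p = 0.460 with an estimated correlation). The complement gene C1qa fell from 65.9 ± 2.49 to 39.4 ± 4.69 FPKM and Lyve1 from 12.4 ± 1.81 to 6.87 ± 0.761 FPKM. Medians in the high-Rn45s and low-Rn45s libraries were 0.33 and 0.41 for fibroblast and -0.55 and -0.66 for macrophage markers. Under scaling to a fixed sum the median was 0.70 for fibroblast and -0.16 for macrophage markers. Of 10 smooth muscle and pericyte markers 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.344). Acta2 rose from 194 ± 48.0 to 779 ± 169 FPKM, while Myh11 had a log2 change of -0.09 and was not called. Of 13 endothelial markers 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0765). Kdr fell from 69.8 ± 7.18 to 43.9 ± 2.65 FPKM. The endothelial list was called lower in 5 of 26 other settings, among them leaving out cre_negative library 1 (adjusted p = 0.0478) or cre_positive library 1 (adjusted p = 0.0304).

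As mean log2(FPKM + 1) over the markers, the fibroblast score was 5.18 ± 0.071 in cre_negative and 5.70 ± 0.106 in cre_positive libraries, the smooth muscle score 4.67 ± 0.117 and 5.31 ± 0.080, the macrophage score 3.57 ± 0.122 and 3.15 ± 0.227 and the endothelial score 5.60 ± 0.115 and 5.41 ± 0.090 (SD, n = 4 per group). The rise of the smooth muscle score came mainly from Cnn1 (log2 change 4.11) and Acta2 (2.01), beside a median of 0.07 over its 10 markers. Each of these 4 scores gave an exact permutation p of 0.0286 (0.0429 adjusted over 6 scores). The erythroid score differed by -0.41 (exact permutation p = 0.0857) and the atrial score by 0.05 (exact permutation p = 0.971). The atrial value was set by 1 library of each group, with differences of 0.71 without cre_negative library 1 and -0.37 without cre_positive library 4 (exact permutation p = 0.114 and 1). Without both cre_negative library 1 and cre_positive library 4, the atrial difference was 0.296 (exact permutation p = 0.1, the smallest that setting allows). Under scaling to a fixed sum the endothelial difference turned to 0.12 (exact permutation p = 0.143) and the macrophage difference shrank to -0.15 (exact permutation p = 0.371). Without cre_negative library 1, 2, 3 or 4, 0 of the 6 scores passed after adjustment and 2 had an exact permutation p under 0.05 before it.

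**Figure D3:**
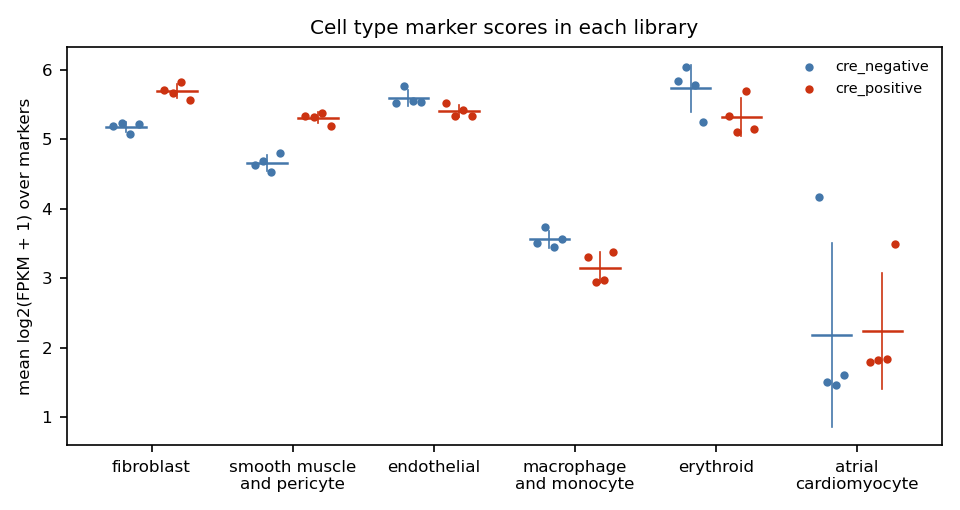
Cell type scores, the mean log2(FPKM + 1) over the markers of a type, for each of the 4 cre_negative and 4 cre_positive libraries, with lines for the group mean and SD. The fibroblast and smooth muscle scores are higher and the macrophage scores lower in cre_positive libraries, the endothelial scores are lower here but turn higher under scaling to a fixed sum, and 1 library of each group stands far above the others in the atrial score.

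Among stress pathways, 9 of 16 genes of the integrated stress response, the program driven by Atf4, rose and 1 fell, with the same counts adjusted over the list alone. The stress response median was 0.45 (camera adjusted p = 0.00266, adjusted p = 0.103 with an estimated correlation). Psat1, an enzyme of serine synthesis, rose from 2.06 ± 0.671 to 5.22 ± 1.51 FPKM and Eif4ebp1, a repressor of translation, from 69.9 ± 3.77 to 141 ± 8.68 FPKM (SD, n = 4 per group). The medians were 0.58 and 0.39 in the high-Rn45s and low-Rn45s libraries and 0.73 under scaling to a fixed sum, and the list was not called at a mean of at least 5 FPKM (adjusted p = 0.0703). Of 17 protein folding genes 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.109). The endoplasmic reticulum chaperone Hspa5 fell from 367 ± 18.7 to 181 ± 10.1 FPKM, and the cytosolic chaperone Hsp90aa1 rose from 116 ± 20.3 to 266 ± 24.4 FPKM. Of 13 p53 targets 7 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.312). The cell cycle inhibitor Cdkn1a rose from 4.53 ± 3.33 to 15.9 ± 4.75 FPKM, with cre_negative library 2 at 9.42 FPKM and the other controls at 2.11 to 3.69 FPKM. Its log2 change was 1.73, or 2.09 without that library. Ccng1 fell from 640 ± 21.3 to 315 ± 28.3 FPKM.

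Of 11 cell cycle genes 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.466). Mcm6 rose by 0.46 on the log2 scale, a call lost in the 5 libraries with high Rn45s alone (adjusted p = 0.130). Of 14 immediate early genes 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.502). Cyr61 rose from 24.0 ± 4.28 to 83.9 ± 6.73 FPKM (SD, n = 4 per group). Of 12 interferon-stimulated genes 1 rose and 3 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.389). Ifit2 rose from 9.08 ± 2.13 to 19.0 ± 1.88 FPKM. Of 8 chemokine and cytokine genes 3 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0883). The list was called lower in 4 of 25 other settings, among them scaling to a fixed sum (adjusted p = 0.00761) and leaving out cre_negative library 1 (adjusted p = 0.0447) or cre_positive library 4 (adjusted p = 0.0330). Csf1, a growth factor of macrophages, fell from 17.8 ± 2.45 to 8.52 ± 0.941 FPKM. Of 10 hypoxia-responsive genes 2 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.403). Egln3 fell from 28.6 ± 3.52 to 10.8 ± 0.555 FPKM and Vegfa from 53.7 ± 3.70 to 33.5 ± 1.58 FPKM. Of 3 tested targets of canonical Wnt signalling Nkd2 rose, from 0.757 ± 0.0861 to 2.05 ± 0.298 FPKM, and 2 were not called, over all genes and adjusted over the list alone.

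Over the 30 lists tested, camera with the preset correlation called 4 higher and 9 lower. With an estimated correlation it called 0, with 9 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0544. Fry, which asks only whether a list's genes move on balance in 1 direction, called 6 higher and 14 lower.

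Further marker lists had few tested genes or few calls. Of 5 erythroid genes 0 were called, over all genes and adjusted over the list alone (camera adjusted p = 0.502). In cre_negative and cre_positive libraries Hbb-b1 stood at 916 ± 539 and 768 ± 72.5 FPKM and Hba-a1 at 652 ± 273 and 515 ± 116 FPKM (SD, n = 4 per group). Both values are uncertain, as reads of the near-identical globin copies can be split. Of 5 atrial markers Dkk3 rose by 0.94 and Stard10 fell by 1.00 on the log2 scale, with the same counts adjusted over the list alone, and the call of Dkk3 was lost in the 5 libraries with high Rn45s alone (adjusted p = 0.0727). That list's median of -0.45 differed in sign from its mean of 0.05 and from camera's upward direction (adjusted p = 0.956). The atrial light chain Myl7 stood at 58.2 FPKM in cre_negative library 1 and 19.6 FPKM in cre_positive library 4, against 0.730 FPKM or less in the other libraries. Of the skeletal muscle markers only Tnnt3 passed the filter, and it rose from 0.142 ± 0.0905 to 6.95 ± 1.69 FPKM. Of the epicardial markers only Wt1 passed the filter, at 1.61 ± 0.418 and 0.920 ± 0.241 FPKM. It was called lower at a limma adjusted p of 0.0407, over all genes and adjusted over the list alone, but not in 13 of 25 other settings. These include leaving out cre_negative library 1, 2 or 3 or cre_positive library 2, 3 or 4 (adjusted p = 0.0934, 0.0770, 0.0930, 0.104, 0.0864 and 0.0574). The tested lymphocyte marker (Cd79b), the adipocyte marker (Car3), the 2 neutrophil markers (S100a8, S100a9) and the 2 Schwann cell markers (Scn7a, Cdh19) were not called, over all genes or adjusted over the list alone. Of 3 nuclear-retained RNAs Tug1 rose by 0.32 and Neat1 fell by 1.35 on the log2 scale, with the same counts adjusted over the list alone. All 4 Y-linked transcripts were expressed in these libraries labelled male, and 2 were called lower, with the same counts adjusted over the list alone (camera adjusted p = 0.522). These were Eif2s3y (log2 change -0.38, limma adjusted p = 0.0499) and Uty (-0.29, limma adjusted p = 0.0213). Eif2s3y was not called in 14 of 26 other settings, with a log2 change of -0.0738 under scaling to a fixed sum, nor without cre_negative library 1, 3 or 4 or cre_positive library 3 or 4 (adjusted p = 0.0992, 0.0701, 0.130, 0.128 and 0.116). Uty turned to 0.00379 under scaling to a fixed sum and was not called without cre_negative library 1 or cre_positive library 3 or 4 (adjusted p = 0.0690, 0.0651 and 0.0639).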

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

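The tests of the Esr1 pattern were chosen after its values were seen. In 23 of 332 groups of 4 libraries, over named genes and cell type scores, 1 library lay far from the other 3. Chance alone gives about 16.6 such groups at 1 in 20. They fell in cre_negative libraries 1 to 4 in 2, 4, 2 and 5 groups and in cre_positive libraries 1 to 4 in 6, 3, 0 and 1 groups.

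In cre_negative library 1, Med4 stood at 29.2 FPKM against 23.8 to 24.1 FPKM in the other controls. The atrial score of that library was 4.17 against 1.47 to 1.60. In cre_positive library 4 the atrial score was 3.49 against 1.80 to 1.84. Cre_negative library 2 held S100a8, a neutrophil gene, at 32.0 FPKM against 1.53 to 2.55 FPKM. The same library had Cxcl12 at 50.8 FPKM against 43.6 to 44.6 FPKM, Tnni1 at 0.0659 FPKM against 0.01 FPKM and an endothelial score of 5.77 against 5.53 to 5.56. Cre_negative library 3 had Med13l at 6.13 FPKM against 4.38 to 4.62 FPKM and Pln at 3028 FPKM against 3490 to 3561 FPKM. In cre_negative library 4, Eda2r stood at 3.39 FPKM against 2.18 to 2.34 FPKM and Cyr61 at 30.4 FPKM against 21.3 to 22.4 FPKM. That library also had Scn7a at 12.4 FPKM against 10.9 to 11.1 FPKM and Mb at 12630 FPKM against 13730 to 13920 FPKM.

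In cre_positive library 1, Rxrg stood at 13.8 FPKM against 24.3 to 26.4 FPKM in the other cre_positive libraries, Thrsp at 11.2 FPKM against 14.7 to 15.4 FPKM and Ckm at 625 FPKM against 729 to 746 FPKM. Values above the others in that library were Lyve1 at 8.001 FPKM against 6.41 to 6.60 FPKM, Timd4 at 0.899 FPKM against 0.415 to 0.456 FPKM and Hbb-b1 at 877 FPKM against 726 to 738 FPKM. In cre_positive library 2, Slc2a1 stood at 14.2 FPKM against 12.4 to 12.5 FPKM, Auh at 45.4 FPKM against 38.8 to 39.8 FPKM and Col3a1 at 145 FPKM against 201 to 208 FPKM.

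Esr1 rose by 3.10 on the log2 scale, and cre_negative library 4 stood at 0.969 FPKM against 0.273 to 0.327 FPKM in the other controls. More cells of a type that holds Esr1 would raise the markers of that type by as much, but the highest rise of a cell type score was 0.647, for smooth muscle markers, which argues against the 6 scored types. Types without a score stay open, among them skeletal muscle, whose only marker to pass the filter, Tnnt3, rose by 2.78. With no filter on low values, the score of 8 skeletal muscle markers went from 0.275 to 0.603, a rise of 0.329. Tnnt3 is 1 of the 8, and its rise accounts for all of this, so the others did not rise on average. The scores of the other types added in that setting rose by 0.0544 or less. The skeletal muscle markers besides Tnnt3 had a mean under 1 FPKM, too low to decide. An Esr1 part carried by an inducible Cre transgene is a candidate explanation. The lowest cre_positive value was 5.96 times the highest control value, but a rise of the mouse's own Esr1 would give such a gap too, and the 2 cannot be told apart, as the values give 1 number for the whole gene and the Cre line is not named. No value here tests which part of Esr1 the reads cover.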

How the results depend on the processing

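Settings chosen after seeing the data were the batch term, the 5 libraries with high Rn45s alone, length and GC trend removed, no small RNA features, and no libraries with atrial transcripts; the cause of a change was not tested unless given. Scaling to a fixed sum gave 5458 genes higher and 1011 lower (3318 calls shared with the deposited scale) and a Med13 log2 change of -0.21 (adjusted p = 0.185); its construction lifts cre_positive values, whose sums were lower. Other settings kept both counts within 1.5 times. Med13 was -0.51 in the libraries with high Rn45s alone (adjusted p = 0.0529), with fewer samples. Leaving out each library gave 1862 to 2335 genes higher and 1862 to 2317 lower. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry 14 lower. The 4 cell type scores called became 0 with a pseudocount of 0.1, no filter, median ratio scaling, quantile normalization, fixed sum, 2M and 2M-2 averaged, and length and GC trend removed, and 0 without the libraries lacking trim, with high Rn45s alone or without atrial libraries, where the smallest exact p is 0.1. Leaving out 1 library gave 0 to 4, 0 for each cre_negative one. Over 6 scores a call needs at least 4 at the smallest exact permutation p, so 1 score can end all calls: the fibroblast score stayed higher by 0.47 to 0.82 and the smooth muscle score by 0.60 to 0.945 (exact permutation p = 0.0286 in each setting that can reach it), while under fixed sum the endothelial and macrophage differences became 0.12 and -0.15. Under fixed sum the log2 change reversed to 0.00296 (Foxo3), 0.00379 (Uty), 0.0188 (Cdh19), 0.136 (Thra), 0.22 (Hbb-b1) and 0.0374 (Hba-a1). Hbb-b1 and Hba-a1 also reversed to 0.29 and 0.0555 (quantile), 0.28 and 0.00117 (without libraries lacking trim) and 0.33 and 0.16 (high Rn45s alone), Hbb-b1 to 0.0135 with 2M and 2M-2 averaged, and it ran from -0.36 to 0.26 leaving out each library, highest without cre_negative library 2. Cd79b reversed to 0.0715 with high Rn45s alone, and Actc1 to -0.0235 with the batch term and to -0.0527 and -0.0123 without cre_negative or cre_positive library 3 (leaving out each library, -0.0527 to 0.0887), against 0.69 (quantile) and 0.34 (fixed sum), both called. Of 125 called named genes, 102 kept call and direction in each setting that tested them (25 or 26). Equal sample numbers of the titles gave no sign of pairing: same-numbered libraries correlated at -0.087, -0.162, -0.126 and -0.078, and none correlated best with its own number. The column names carry in part other numbers, and a pairing by those was not tested. A replicate block gave 1963 genes higher and 1899 lower, 3804 shared. Cell type scores were not run with the block or the batch term. At 1 FPKM the shallowest library holds 9.02 fragments for 2 kb, which limits low genes.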

Other observations

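The genes in the next paragraph were chosen after their values were seen, as were the tests of the muscle, energy and matrix lists and of Myh7. The count of other splits was planned before the data were examined. Gene families by symbol were an exploratory scan.

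The myosin light chain Myl1 rose from 103 ± 12.8 to 370 ± 48.9 FPKM, the fast myosin-binding protein Mybpc2 from 9.54 ± 2.27 to 26.2 ± 4.86 FPKM and the skeletal calsequestrin Casq1 from 24.0 ± 6.11 to 86.1 ± 9.44 FPKM (SD, n = 4 per group). Dio2, which makes active thyroid hormone, rose from 1.08 ± 0.316 to 8.38 ± 2.44 FPKM, while the thyroid hormone receptors Thra and Thrb were not called (limma adjusted p = 0.176 and 0.615). Myoglobin (Mb) fell from 13537 ± 609 to 4012 ± 250 FPKM, muscle creatine kinase (Ckm) from 1623 ± 195 to 711 ± 57.7 FPKM and its mitochondrial counterpart Ckmt2 from 1819 ± 258 to 953 ± 71.1 FPKM. Plin5, a lipid droplet protein, fell from 77.5 ± 28.6 to 16.4 ± 4.82 FPKM. Opa1, Mfn1 and Mfn2, which fuse mitochondria, fell by 0.85, 0.65 and 0.62 on the log2 scale. Ankrd1, a stress-responsive sarcomere protein, rose from 1128 ± 384 to 4401 ± 923 FPKM and periostin (Postn) from 33.4 ± 5.05 to 168 ± 31.8 FPKM.

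Of 179 gene families with at least 8 tested genes, camera called 4 higher and 9 lower with the preset correlation, and 0 with an estimated correlation. Among 48 large mitochondrial ribosomal proteins (Mrpl) 36 fell and 1 rose, and among 29 small ones (Mrps) 21 fell and 0 rose. Their median log2 changes were -0.52 and -0.49, and their adjusted p was 0.905 with an estimated correlation. Of 9 Coq genes, which make coenzyme Q, 8 fell and 0 rose (median -0.87, adjusted p = 0.905 with an estimated correlation). Of 8 annexins (Anxa) 6 rose and 0 fell, and of 10 ESCRT genes (Chmp) 7 rose and 0 fell, with medians of 0.61 and 0.30 (adjusted p = 0.905 with an estimated correlation). Scaling to a fixed sum moved these 5 medians to -0.21, -0.18, -0.56, 0.92 and 0.61. Of the other called families, that of Timm turned from -0.26 to 0.0277 and that of Cox went from -0.35 to -0.0343 under that scaling.

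The 8 libraries can be split into 2 groups of 4 in 35 ways. For genes called higher (2307) and for genes called lower (2269), only the real split gave as many in 1 direction. That is 1 of 35, the smallest share possible, and the highest of the others gave 1 gene. Each of the others mixes libraries of both groups, so the group difference widens their spread. Their low counts therefore do not by themselves exclude chance. For gene lists called with the preset correlation, each split was counted by its direction with more lists. At least 4 lists, as many as were found higher, were reached by 23 of 35 splits. At least 9, as many as were found lower, were reached by 11 of 35. The 4 are the smaller direction of the real split, so for them this is no like comparison. The highest of the other splits gave 13 in each case, so over all 35 splits chance cannot be excluded for these 2 counts of lists. The splits that reached 9 or more hold 3 libraries of 1 group and keep part of the group difference. In the 18 splits with 2 libraries of each group, at most 6 lists were called in 1 direction and 8 in all, with a median of 4. Such splits balance the groups, so the preset correlation let lists be called without a difference of group. The real split gave 9 lower and 13 in all. Its 4 higher lists do not exceed the 6, which again count the larger direction of a split.

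Of the 13 lists called with the preset correlation, among them those of muscle, energy supply and matrix, 9 lay lower and 4 higher, and with an estimated correlation 0 were called (smallest adjusted p = 0.0544). A lower share of cardiomyocytes would by itself raise the other cell types alike. The fibroblast score instead rose against the endothelial score by 0.703, from -0.42 ± 0.105 to 0.29 ± 0.0964 (SD, n = 4 per group). Its exact permutation p of 0.0286 adds no evidence, since the fibroblast rise and the endothelial fall each gave that value. Of 10 fibroblast markers 5 rose and 1 fell, and the scores do not part cell share from expression per cell. The gap therefore cannot decide whether a lower share of cardiomyocytes set the falls of the muscle and energy lists. A lower share alone would lower genes made mainly by cardiomyocytes by a like amount. In the sarcomere and Z disc list 13 of 21 genes fell, 1 rose and 7 were not called. Their log2 changes ran from -1.67 to 1.08, which argues against a lower share as the only cause in that list. A part in the falls stays open. After the trend of each library with transcript length and GC content was removed, 13 of these 13 lists kept call and direction with the preset correlation. An effect of Cre itself cannot be told apart from the deletion, because only cre_positive mice carry it. Of 13 p53 targets, which damage by Cre might raise, 7 rose and 4 fell. Camera did not call the list (adjusted p = 0.312), whereas fry did (adjusted p = 2.2e-04), so this list does not decide the question.

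Myh7 was not raised beside Nppa and Nppb, at 6.27%, 3.14%, 5.82% and 3.84% of Myh6 in cre_negative and 10.2%, 8.41%, 8.58% and 9.11% in cre_positive libraries 1 to 4. The SD of its log2 values over the controls, 0.751, lay above that of each of 534 genes of like length (highest 0.590), so its control level is unsteady. Myh6 reads counted as Myh7 could hide a rise. If their share were equal in all libraries, taking off the largest the controls allow, 3.14% of Myh6, would uncover it. With that share removed, 2 of the 4 controls, at 177 and 178 FPKM, still lay above each cre_positive library (87.4 to 123 FPKM), and the other controls fell to 0 and 31.4 FPKM. Removing the length and GC trend left a log2 change of -0.69 (limma adjusted p = 0.0804). A share that differs between libraries, and reads of the antisense Mhrt, could still set part of these values and stay open.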
